A study of Rattus norvegicus with 3 samples.

How the data were processed

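RNA sequencing profiles of 3 libraries of the rat beta-cell line INS-1 832/13 were examined, 1 library for each of the overexpressed proteins β-Gal, NIK and NIK(KA). Groups were taken from the sample titles. Every group holds 1 library, so there is no replicate error, no p-value is given, and every difference is between 2 libraries rather than between 2 conditions.

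The deposited files give 1 FPKM value (a read number scaled to the length of the gene model and to the library total) for each gene model and library, as computed by the authors. TopHat2 and HTSeq 0.6.1 are named in the submitters' processing notes, as an aligner and a read counter, and the version of TopHat2 is not given in the sources used here. The same notes name the mouse build GRCm38, whereas the rows of the files are rat Ensembl gene IDs, so the build behind the values is not settled by the sources used here and no coordinates are given. Each file lists the same 34340 gene models, of which 32883 carry a rat Ensembl ID and 1457 carry another ID, not paired with an annotated gene in the files. Library preparation, strandedness and filters are not given in the sources used here, so reads from overlapping or antisense genes and from near-identical copies cannot be separated.

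The files do not pair IDs with gene symbols. The reference table used here lists 47357 genes of the assembly GRCr8 and gives an Ensembl ID for 0 of them, so 0 of the gene IDs were matched to a symbol. The 26 gene lists fixed before the data were examined, the rule for naming genes and the check on the gene of NIK all needed symbols and were therefore not run. At most 2 gene models that were higher and 2 that were lower are printed by ID. The first 3 of these were taken by size, as the 2 Ensembl gene models with the largest and the 1 with the smallest ratio of NIK to β-Gal on the log2(FPKM + 1) scale. The other was taken because it had the highest FPKM in the β-Gal library. This narrower rule was set after the values were seen.

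FPKM is a read number divided by gene length and library total, so the number of reads behind each value was worked out from the FPKM steps. Gene models with equal low read numbers in all 3 libraries (107 of them) gave the library totals as a common divisor, and the lengths and read numbers followed as the lowest whole numbers that give the deposited values. All of the 22026 gene models above 0 (100.0%) came out whole, within a tolerance of 1e-06 reads and with lengths of at most 100000 bases. With totals wrong by 1 part in 10000, 0.334% of the gene models above 0 in 2 or 3 libraries came out whole. The lowest whole numbers added up to 96.1%, 95.9% and 95.9% of the totals for β-Gal, NIK and NIK(KA), because numbers that share a divisor with the length are given too low. Read numbers and lengths printed here are thus lower limits, and the intervals made from them are if anything too wide. On simulated data with 22026 gene models the 3 totals were recovered, 92.7% of the gene models had the simulated read numbers, and the lowest whole numbers held 95.9% of the reads.

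Library totals were 17457498 reads for β-Gal, 15095979 for NIK and 14349721 for NIK(KA). One read on a gene model of 1000 bases was worth 0.0573, 0.0662 and 0.0697 FPKM in the same order, and 3 reads, the limit that a count of 0 allows, 0.172, 0.199 and 0.209 FPKM. Intervals of a ratio are exact 95% intervals of Clopper and Pearson on the split of the reads between 2 libraries. They cover counting error only, and reads are not independent molecules.

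Ratios are log2((FPKM + 1) / (FPKM + 1)), which understates the change of low genes. By rules fixed before the data were examined, the 11171 gene models with an FPKM of at least 5 in at least 1 library were compared, and a gene model was counted as higher or lower at a 2-fold difference on that scale. A library was said to stand apart for a gene model if it was at least 2-fold above or at least 2-fold below both others, and the same count was made for each library in turn. To show what counting error alone gives, 100 sets of 3 libraries were drawn from 1 common Poisson rate per gene model at the observed totals. Simulated changes in NIK were counted by the same rule for 49 of 49 gene models set 4-fold higher, 48 of 48 set 3-fold higher, 43 of 44 set 3-fold lower and 46 of 46 set 4-fold lower, and for 26 of 10500 unchanged ones. Changes were set only in gene models above a minimum number of reads over the 3 libraries. The shares of changes found therefore do not cover gene models with few reads.

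Alternatives were other pseudocounts (0.1, 0.5 and 5), other minimum FPKM values (none, 1 and 20) and other fold thresholds (1.5 and 3). Other scalings were FPKM rescaled to equal sums as TPM, an equal upper quartile, and medians set to 0. The last set to 0 the median log2 ratio of each library to the mean log2 FPKM of the 3 libraries. It used the gene models with an FPKM of at least 5 in every library. The median between 2 libraries then need not be 0. Further alternatives, chosen after seeing the data, kept gene models with a recovered length of at least 300 bases, kept those with at least 50 reads in 1 library, rescaled without 1 abundant gene model, or rescaled to equal sums at the mean FPKM sum of the 3 libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.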

Results

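INS-1 832/13 is a glucose-responsive clone of a rat insulinoma line and is widely used as a model of the pancreatic beta cell. Transcript levels were measured by RNA sequencing in cells that overexpressed β-Gal (β-galactosidase, a common control protein), NIK (NF-κB-inducing kinase, which activates the non-canonical NF-κB pathway) or NIK(KA). The labels do not describe NIK(KA). In published work this name is used for a form of NIK with a lysine-to-alanine change in the kinase domain that lacks kinase activity. Each condition was profiled in 1 library. The β-Gal library held 17457498 counted reads, the NIK library 15095979 and the NIK(KA) library 14349721.

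The libraries were similar in breadth. Of 34340 gene models, 19199 were above 0 in β-Gal, 19839 in NIK and 20039 in NIK(KA), and 10110, 10242 and 10291 reached an FPKM of 5. The 10 gene models with the most recovered reads took 5.80% of the recovered reads in β-Gal, 4.63% in NIK and 5.19% in NIK(KA). The gene models without an Ensembl ID took 1.36%, 1.48% and 1.39% of the recovered reads in the same order. Recovered reads are the lowest whole numbers described above, so these shares are approximate and are not shares of the library totals. Gene symbols are not paired with the IDs in the files, so the level of the gene of NIK, which would check the labels, is not reported.

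The first comparison asked which transcripts differed when NIK was overexpressed, with the β-Gal library as the control. Among 11171 gene models, 752 (6.73%) were at least 2-fold higher in NIK than in β-Gal and 458 (4.10%) were at least 2-fold lower. The higher group held 229 gene models beyond 4-fold and 83 beyond 8-fold, and the lower group held 59 and 10. The largest single difference lay on the lower side, at a log2 ratio of -10.55, compared with 6.56 on the higher side. Of the gene models in the higher group, 117 (15.6%) had an FPKM below 1 in β-Gal. The median FPKM of the higher group was 4.61 in β-Gal and 18.2 in NIK, and that of the lower group was 18.6 in β-Gal and 5.94 in NIK.

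The gene model ENSRNOG00000019660 had the largest ratio of NIK to β-Gal on the log2(FPKM + 1) scale, at 6.56. That scale holds down gene models near 0 in β-Gal, so the rank applies to that scale alone. Ratios given as folds with an interval are of FPKM itself, without the pseudocount. For this gene model the FPKM was 0.975 in β-Gal (45 reads) and 185 in NIK (7386 reads), a ratio of 190-fold (95% counting interval 142 to 260). In NIK(KA) it was 1.11 (42 reads), and its ratio of NIK(KA) to β-Gal was 1.14 (0.728 to 1.77), an interval that includes 1. The next on that scale, ENSRNOG00000018735, had an FPKM of 3.25 in β-Gal (58 reads), 255 in NIK (3928 reads) and 3.34 in NIK(KA) (49 reads). Its ratio of NIK to β-Gal was 78.3-fold (60.5 to 103), and its ratio of NIK(KA) to β-Gal was 1.03 (0.688 to 1.53).

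On the lower side, ENSRNOG00000014166 was read almost only in the β-Gal library. Its FPKM was 1850 there (89799 reads, 0.514% of the library total), 0.238 in NIK (10 reads) and 0.175 in NIK(KA) (7 reads). The ratio of β-Gal to NIK was 7765-fold (4222 to 16194). The ratio of NIK to NIK(KA) was 1.36 (0.467 to 4.20), an interval that includes 1. ENSRNOG00000012052 had the highest FPKM of all gene models in the β-Gal library, at 8321 (64646 reads). It was 2860 in NIK (19210 reads) and 4931 in NIK(KA) (31485 reads). It was thus 2.91-fold lower in NIK than in β-Gal (2.86 to 2.96) and 1.69-fold lower in NIK(KA) than in β-Gal (1.67 to 1.71), and NIK was 1.72-fold below NIK(KA) (1.69 to 1.76).

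**Figure D1:**
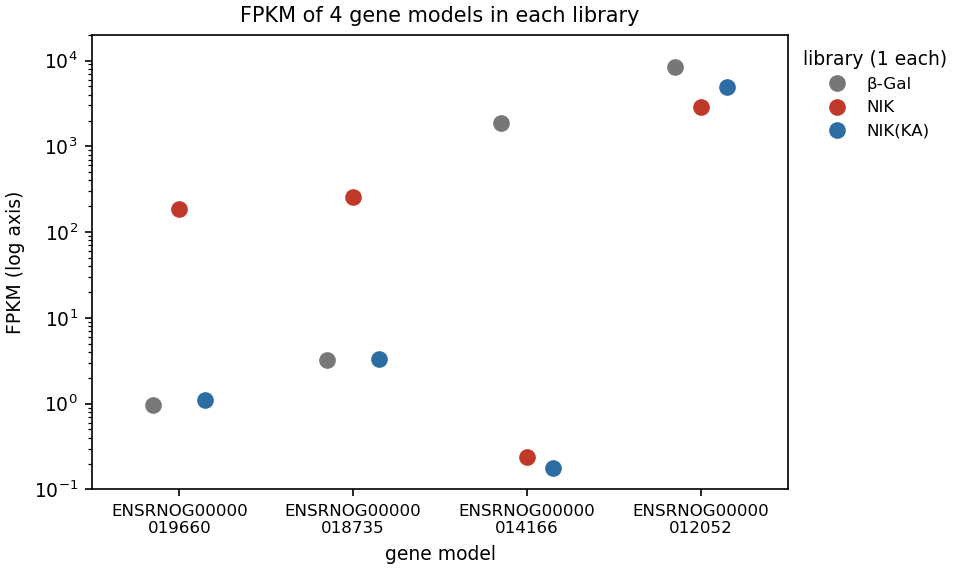
FPKM (log axis) of 4 gene models, with 1 point for each library and no error bars because each condition has 1 library. ENSRNOG00000019660 and ENSRNOG00000018735 are high in NIK alone (185 and 255), ENSRNOG00000014166 is high in β-Gal alone (1850), and ENSRNOG00000012052 runs from 8321 in β-Gal through 4931 in NIK(KA) to 2860 in NIK.

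Counting error accounted for few of these differences. Sets drawn from 1 common rate per gene model gave at most 24 higher and 21 lower. The 95% counting interval of the ratio excluded 1 for 742 of the 752 higher and 440 of the 458 lower gene models. The gene models were chosen from the same reads for being at least 2-fold apart, so such intervals are no separate check, here or in the comparisons below. These figures compare the 2 libraries and say nothing about the spread between cultures, for which there is no replicate check.

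The second comparison set the NIK(KA) library against the same control and asked what overexpression of that form was accompanied by. Fewer gene models differed by size than in the first comparison: 332 (2.97%) were higher in NIK(KA) than in β-Gal and 218 (1.95%) were lower. Beyond 4-fold there were 44 higher and 51 lower, and beyond 8-fold 10 and 20. The counting interval excluded 1 for 319 of the higher and 208 of the lower gene models, and sets drawn from 1 common rate gave at most 20 and 21. With the median log2 ratio of each library to the mean of the 3 libraries set to 0, the counts became 276 higher and 278 lower. That scaling shifted the ratios of NIK(KA) to β-Gal further down than their median log2 FPKM ratio of 0.05. An equal upper quartile gave 367 higher and 197 lower, TPM 546 and 312, and equal sums at the mean FPKM sum 332 and 218. The excess of higher over lower gene models was thus lost under the first of these scalings only. Short gene models, of under 300 bases, made up 16.3% of the higher and 16.5% of the lower group, compared with 4.17% of all gene models compared. In the first comparison their shares were 5.32% and 9.83%, and in NIK versus NIK(KA) they were 4.36% and 16.1%. The recovered lengths are lower limits, so some longer gene models may fall under 300 bases and all these shares are upper limits.

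The third comparison, of NIK with NIK(KA), addressed the difference between the 2 forms of the kinase. In NIK, 779 gene models (6.97%) were at least 2-fold higher than in NIK(KA), and 236 (2.11%) were at least 2-fold lower. The higher group held 284 gene models beyond 4-fold and 110 beyond 8-fold, compared with 29 and 7 in the lower group. Its median FPKM was 20.6 in NIK and 4.97 in NIK(KA). The median log2 ratio of all gene models compared was -0.12. With the median log2 ratio of each library to the mean of the 3 libraries set to 0, there were 856 higher and 182 lower gene models. That scaling removed only a part of the shift between these 2 libraries. The counting interval excluded 1 for 770 of the 779 higher and 224 of the 236 lower gene models.

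**Figure D2:**
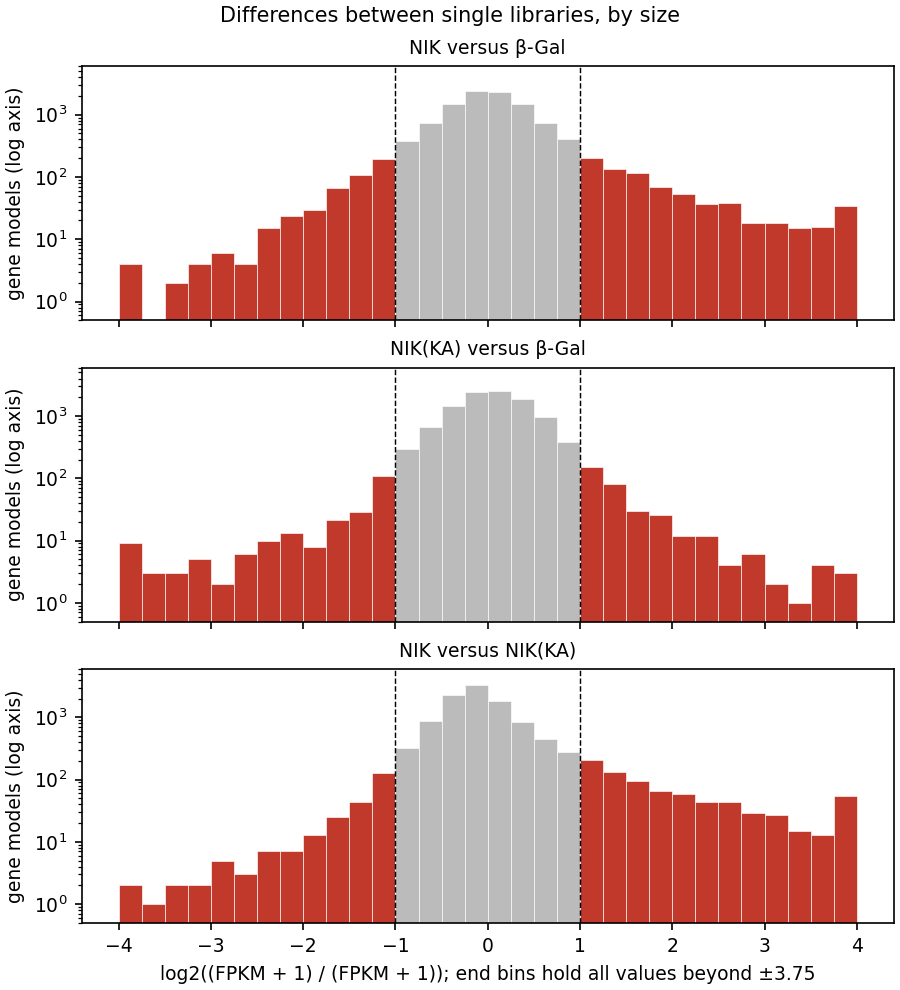
Number of gene models (log axis) by log2((FPKM + 1) / (FPKM + 1)) in bins of 0.25, with all values further out collected in the end bin on each side, for each of the 3 comparisons of single libraries over the same 11171 gene models, with the first-named library over the second. Bars beyond the dashed lines (red) are at least 2-fold apart, and more gene models lie beyond 8-fold on the higher side in both comparisons that involve NIK (83 and 110) than in NIK(KA) versus β-Gal (10).

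The 3 libraries were then compared together. NIK stood apart from both other libraries for 647 gene models, of which 543 were above both and 104 below both. β-Gal stood apart for 201 gene models (104 above and 97 below) and NIK(KA) for 164 (76 above and 88 below). In sets drawn from 1 common rate the highest counts were 18 for NIK, 16 for β-Gal and 15 for NIK(KA). These sets hold counting error alone and no spread between cultures, so they are not what separate cultures without an effect would give. Of the 752 gene models higher in NIK than in β-Gal, 543 (72.2%) were thus also higher in NIK than in NIK(KA). The 2 lists share the NIK library. Counting error alone gave at most 11 such gene models, and independent lists of these sizes would share 52.4. Of the 458 gene models lower in NIK than in β-Gal, 104 (22.7%) were also lower in NIK than in NIK(KA). Here counting error alone gave at most 12 and independent lists would share 9.68. The simulated lists held means of only 12.2 higher and 12.9 lower gene models in NIK versus β-Gal, so their overlaps could not come near those observed. Independent lists leave out the shared library. Neither figure thus shows whether the overlaps exceed what sharing the NIK library gives.

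**Figure D3:**
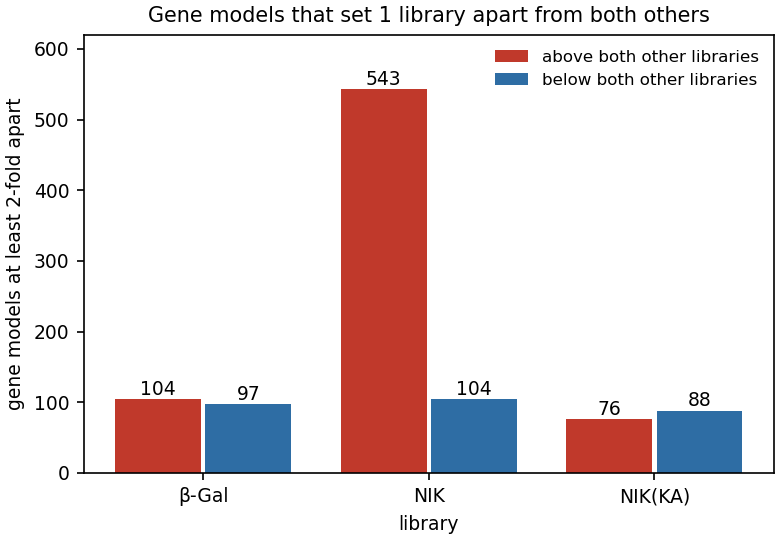
Number of gene models for which 1 library was at least 2-fold above (red) or at least 2-fold below (blue) both others. The NIK library was above both others for 543 gene models, and the 5 other counts lie between 76 and 104.

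The higher and lower groups of the first comparison stood differently in the NIK(KA) library. For the 752 gene models higher in NIK, the median log2 ratio of NIK(KA) to β-Gal was 0.07 (quartiles -0.25 and 0.51), and 516 of them (68.6%) were within 1.5-fold of β-Gal. For the 458 gene models lower in NIK, the median log2 ratio of NIK(KA) to β-Gal was -0.68 (quartiles -0.97 and -0.45), and 181 (39.5%) were within 1.5-fold of β-Gal. Of all 11171 gene models compared, 80.5% were within 1.5-fold, so the shares of both groups lay below that of gene models at large. With the median log2 ratio of each library to the mean of the 3 libraries set to 0, the medians were 0.02 and -0.75. That scaling shifted the ratios of NIK(KA) to β-Gal further down than their own median. Gene models called in both NIK and NIK(KA) against β-Gal numbered 97 higher and 104 lower. Independent lists would share 22.3 and 8.94, and counting error alone gave at most 12 and 10. The simulated sets held at most 24 higher and 21 lower gene models in NIK versus β-Gal, so they could not give overlaps near those observed. Neither independent lists nor simulated sets allow for the spread between cultures. Both comparisons use the same β-Gal library, which cannot be split, so how much of the overlap comes from that library cannot be told.

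Across the 11171 gene models, the log2 ratios of NIK to β-Gal and of NIK(KA) to β-Gal had a Pearson correlation of 0.39. Sets with counting error alone gave a mean of 0.46, taken over a part of the 100 sets. The 2 ratios that share NIK had a correlation of 0.72 (0.52 from counting error alone) and the 2 that share NIK(KA) one of 0.36 (0.52). Ratios that share a library correlate even without a common effect, whatever the size of the error. The correlations therefore show neither a common effect nor how much counting error contributed, whereas covariances do depend on the size of the error. The covariance of the ratios that share β-Gal was 0.156, compared with 0.00853 from counting error alone. The corresponding covariance of the 2 ratios that share NIK was 0.382, compared with 0.00972, and that of the 2 ratios that share NIK(KA) was 0.142, compared with 0.0102. Gene models are not independent replicates, and with 1 library per condition these covariances include whatever was particular to the shared library.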

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

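The tests of the gene model read almost only in β-Gal by its gap to the next one, and of a β-Gal culture that differed by itself, were chosen after the results were seen. The other tests were set down before.

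Gene models called in opposite directions in NIK and in NIK(KA), each against β-Gal, numbered 24, of which 22 were higher in NIK and lower in NIK(KA) and 2 were the reverse. Counting error alone, without any spread between cultures, gave at most 3 of either kind. Its lists were far shorter than those observed, with means of 12.2 higher and 12.9 lower in NIK versus β-Gal, so this is no yardstick for the 24. Independent lists of the observed sizes would share 14.7 and 13.6. They leave out that both comparisons share the β-Gal library, so they are no yardstick either. The difference between the 2 effects was not tested, since there is 1 library of each.

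The NIK library stood apart from both others for 647 gene models, 3.22 times as many as the next library. The values argue against counting noise, the unequal depth of these libraries and 1 constant scaling factor per library as explanations. Counting noise gave at most 18 such gene models in 100 simulated sets. With every library thinned to 14349721 reads the NIK library stood apart for 650 and the next library for 214. With the median log2 ratio of each library to the mean of the 3 libraries set to 0, the counts were 654 and 216. The NIK library held 15095979 reads before thinning, so thinning changed it little. Scaling by 1 factor per library cannot show bias that varies with level or length. A difference between cultures or library preparations cannot be told apart from the overexpressed protein, because there was 1 library per group, and the effect of NIK itself stays open as untested.

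ENSRNOG00000014166, with 89799 reads in β-Gal and 10 and 7 in the other libraries, lay 10.55 units above both on the log2(FPKM + 1) scale, on which its excess is smaller than in FPKM itself, and the next gene model with an excess in β-Gal lay 4.83 above, a gap of 5.71. The gap restates the pattern and decides nothing about its source. A transcript brought in by the overexpression construct and a gene active in that culture alone both stay open, since the ID is not paired with a gene name and the construct is not described. Reads moved to 1 other gene model are argued against, since no other gene model gained more than 14.1% of the lost reads in both other libraries. Among gene models with at least 50 reads in a library, the largest excess shared by NIK and NIK(KA) over β-Gal on that scale was 3.39 (FPKM 2.17 in β-Gal, 32.2 in NIK and 75.6 in NIK(KA)). The next had 0 reads in β-Gal, 53 in NIK and 73 in NIK(KA), so its excess is limited by the pseudocount.

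The gene models lower in NIK than in β-Gal were mostly lower in NIK(KA) too, with a median log2 ratio of -0.68 to β-Gal, and NIK(KA) lay between the other libraries for 87.3% of them, compared with 47.2% of the gene models higher in NIK. Counting noise in the shared β-Gal library gave a median of -0.013 in simulated sets in which NIK(KA) and β-Gal had the same rates, which argues against it. A β-Gal culture or library that was itself unusual cannot be told apart from an effect common to both NIK proteins, because the same single β-Gal library enters both ratios.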

How the results depend on the processing

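Of 135 alternative counts, 80 stayed within 1.5 times the reported count. Counts below are in the order higher and lower in NIK versus β-Gal, higher and lower in NIK(KA) versus β-Gal, higher and lower in NIK versus NIK(KA), then apart in β-Gal, NIK and NIK(KA), and those within 1.5 times are left out where said. A pseudocount of 5 gave 465, 215, 129, 93, 516, 57, 66, 376 and 64, and one of 0.1 moved only the last, to 252. A minimum FPKM of 1, and no minimum, gave 1192, 705, 800, 372, 1119, 556, 362, 942 and 372, where 1119 and 942 lie within 1.5 times. With a pseudocount of 1, a 2-fold difference already needs an FPKM of at least 1. These 2 settings are thus the same by arithmetic, though each is counted among the alternatives. A minimum of 20 gave 359, 216, 137, 119, 402, 78, 89, 314 and 84. A threshold of 1.5-fold gave 1599, 1282, 1288, 885, 1345, 989, 944, 1401 and 658, and one of 3-fold gave 370, 129, 90, 71, 411, 55, 49, 313 and 59. Rescaling to equal sums (TPM) raises all values, so that the fixed minimum and pseudocount act less strongly as well; it gave 546 higher in NIK(KA) than in β-Gal, 400 lower in NIK than in NIK(KA), 320 apart in β-Gal and 281 apart in NIK(KA). Equal sums at the mean FPKM sum, chosen after seeing the data, gave 332, 231, 200 and 162 for these. The other settings, including those chosen after seeing the data, kept all counts within 1.5 times. The NIK library stood apart most often under all 15 alternatives, by 1.48 to 5.70 times the next library. Of 72 alternative ratios of the 4 named gene models, 58 moved by at most 0.5 of the width of the counting interval on the log2 scale and 14 by more. One changed sign, that of ENSRNOG00000018735 in NIK(KA) versus β-Gal, from 0.03 to -0.03. This was with the median log2 ratio of each library to the mean of the 3 libraries set to 0. The gene model was not called in either setting. Leaving out a replicate was not possible with 1 library per group, and the alternatives for gene lists were not run because no symbols were matched. Depth limits low gene models most: 3 reads on 1000 bases are worth about 0.172 to 0.209 FPKM.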

Other observations

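Gene models without an Ensembl ID made up 3.40% of the 11171 compared and a larger share of every called group: 8.51% of those higher and 8.73% of those lower in NIK than in β-Gal, 8.13% and 9.63% in NIK(KA) versus β-Gal, and 7.45% and 12.7% in NIK versus NIK(KA). Their recovered reads differed little in total between libraries (1.36% to 1.48% of all recovered reads).

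Few of the most abundant gene models were at least 2-fold higher than in β-Gal. The library used for the ranking enters the ratios, so the 100 gene models with the highest FPKM were taken from each library in turn. In NIK versus β-Gal, ranking by β-Gal gave 0 higher and 5 lower (median log2 ratio -0.10), ranking by NIK gave 1 and 2 (0.03), and ranking by NIK(KA) gave 0 and 2 (-0.01). In NIK(KA) versus β-Gal, the same rankings gave 0 and 4 (-0.01), 0 and 3 (0.03), and 2 and 0 (0.07). Of all 11171 gene models, 6.73% were higher and 4.10% lower in NIK than in β-Gal, and 2.97% and 1.95% in NIK(KA). The higher counts among the most abundant lay below these shares, and the lower counts lay above or below them depending on the ranking.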
